A study of Arabidopsis thaliana with 8 samples.

How the data were processed

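Leaf RNA of Arabidopsis thaliana was measured on 8 single-colour (Cy3) Agilent arrays of 43803 non-control spots each. Per the labels, plants of the wild type Col-0 and of the mutant At-med16-1, which carries a defect in subunit 16 of the Mediator complex, were infiltrated by syringe with Pseudomonas syringae pv. tomato DC3000 carrying the avirulence gene avrRpt2, and leaves were taken at 0, 4, 8 and 24 h. RNA of 3 biological replicates was mixed in equal amounts before hybridisation, so each genotype and time has 1 array and there are no replicate arrays. No mock-infiltrated arrays were analysed here, and harvest clock times are not given in the sources used here. The effects of the inoculation, of elapsed time and of time of day were therefore not separated. Per the file headers, the 4 mutant arrays lay on one slide and the 4 wild-type arrays on another, with the same order of times on both, so slide and genotype cannot be told apart.

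Spot signals were taken from the scanner files, whose values are in intensity units per the file headers. They had been background-subtracted and corrected for spatial trends within the array by Agilent Feature Extraction 10.1.1.1 per the submitters' processing notes, without scaling between arrays. The deposited series value table is on a log2 scale with the same median in every column; the steps that made it are not given in the sources used here, and it served only as an alternative. Its columns correlated with the log2 scanner signals between r = 0.983 and 0.985 across probes.

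The log2 processed signal was shifted by the 75th percentile of its array. Spots marked as non-uniform or population outliers were left out, which concerned 651 probes on at least 1 array. Of the 43603 distinct probes, 38413 were named for a locus, and 5190 probes without a locus name were left out. One probe stood for each of 28805 loci, the one well above background on the most arrays and then the brightest. Chromosome positions were not analysed here beyond the order of locus names, since no genome of the array's build was used here.

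A total of 22567 loci with a probe well above background on at least 2 of the 8 arrays were tested in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) for reading the files. Loci saturated on all 8 arrays were left out, and other saturated signals entered limma as read. Time and genotype were additive terms, variances were moderated with an intensity trend, and 3 residual degrees of freedom remained. The ± values are standard errors of the limma coefficient. The change of the genotype difference from 0 h to the later times was a further term (the interaction), with 2 residual degrees of freedom. It set 4, 8 and 24 h together against 0 h. Since the labels call the 0 h plants infected too, it does not compare inoculated with uninoculated plants. Adjusted p values are two-sided and follow Benjamini and Hochberg at a threshold of 0.05. Comparisons of 1 array with another have no test and were counted at 2-fold or more. Where a group was not well above background, its fold is given as "at least N-fold": the mean of the bright group was set against the mean of, per array of the dim group, the higher of the array's lowest well-above-background signal and the probe's own signal. These folds are bounds by this rule only and vary with that lowest signal. Dim probes can read above it, as GOLS3 did on the mutant 4 h array (−7.66 against −9.28).

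Where only part of a group was dim, the fitted value is given, with the value after raising dim signals to the floor of their array where the 2 differ. Gene lists with 303 genes were fixed before the data were examined, as were the comparisons, the rule for named genes and all alternatives but one. They cover salicylic acid synthesis with the EDS1 and PAD4 node, output genes of systemic acquired resistance (SAR), positive and negative SAR regulators, jasmonate/ethylene defence genes, jasmonate synthesis with JAZ repressors and the MYC branch, camalexin, pattern-triggered signalling, recognition of AvrRpt2, endoplasmic reticulum folding, the CBF cold regulon, the clock, photosynthesis, Mediator, senescence, iron, phenylpropanoids, flavonoids, aliphatic glucosinolates, heat shock, touch, reference genes, and markers of guard cells, epidermis, phloem, xylem, trichomes and root. Values existed for 296 of these genes. The 7 genes without one were PR5, ASB1, GSTF6, PDIL2-1, LHCB1.2, RBCS3B and ZAT10, and MYB12, GL1, EXP7, PIN2 and PLT1 had values but were too dim to be tested. The SAR regulator, jasmonate/ethylene and CBF lists were chosen with general knowledge of published work on this mutant, and whether that work used these arrays is not given in the sources used here. Their counts are therefore not independent evidence.

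For genotype and for the interaction, camera compared each list with all other genes. It was run with a preset correlation of 0.01, and again with an estimated correlation. The latter version also refers its statistic to the few residual degrees of freedom of the fit. A call lost with it is therefore not by itself a sign of correlation between members. Fry does not compare a list with other genes; it tests whether members move one way on balance against no change. Where the text gives 1 count for a list, the count adjusted over the list alone was the same. For single arrays, a list's median was placed among 10000 random lists drawn from the same 20 bins of expression. These were drawn gene by gene and do not keep the correlation between members of a list. A place below or above all of them is therefore a description and not a p value. Named genes were MED16, RPS2, ICS1, NPR1, PR1, PR2, PR5 and PDF1.2a; the 10 largest rises and 10 largest falls past the threshold between genotypes with 1 direction at all 4 times; the 5 largest differences each way between genotypes at each time; the 5 largest rises and falls past the threshold at each later time with 1 direction in both genotypes; up to 10 each way for the interaction; and up to 4 members of a list with the largest change. These largest changes were taken by fitted value or single-array bound, and the order among genes dim on some arrays is not fixed. Outside this rule, chosen after their values were seen, were ERF1, KIN1, KIN2, CBF1, CBF2, CBF3 and AOC2 between genotypes, SNI1 and NIMIN3 at 4 h, and DIR1, PDF1.2c and PDF1.3 at 8 h.

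Alternatives were normal-exponential background correction (offset 50), quantile scaling, scaling to the median of genes well above background on all 8 arrays, the series value table, a filter for signal on all 8 arrays, no filter, the mean of all probes, a 1.5-fold rule, no time term, time as a random block, other variance moderation, leaving out each time in turn and the estimated list correlation. The normal-exponential version was run on median spot signals and chosen after seeing the data, because the mean signal planned for it is not a column of the files used here. On simulated data with 200 changed genes among 22567, the genotype test recovered 58.2% of genes changed by 1 log2 unit, 94.0% at 2 and 100% at 4, and 6.15% of its calls were unchanged genes. For 4 h against 0 h recovery was 20.9%, 91.0% and 95.5%, with 6.76% of calls unchanged, and for the interaction 0%, 19.4% and 78.8%, with 4.41%. The simulated noise was independent between genes and arrays, without a shared slide effect, and far fewer genes changed than the 9615 called at 4 h. These shares hold only for such data.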

Results

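The arrays followed leaves of wild-type Arabidopsis and of the At-med16-1 mutant after inoculation with Pseudomonas syringae carrying avrRpt2, whose product is recognised through the resistance protein RPS2. MED16 is a tail subunit of Mediator, the complex that links transcription factors to RNA polymerase II, and is also known as SFR6, a gene needed for freezing tolerance. There was 1 array for each genotype at each of 0, 4, 8 and 24 h, made from pooled RNA, and no replicates. Between 67.9% of spots (mutant, 8 h) and 79.0% (wild type, 24 h) were well above background. The 75th percentile of the signal lay between 2425 (mutant, 0 h) and 10783 (wild type, 24 h), and between 27 and 168 spots per array were saturated. Arrays of the same time correlated across genes between the genotypes at r = 0.981, 0.968, 0.978 and 0.979 for 0, 4, 8 and 24 h, against 0.807 to 0.932 between times within the wild type and 0.827 to 0.957 within the mutant. The number of arrays limits the precision of every value.

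The mutated gene and the best-known defence genes were examined first. MED16 signal (AT4G04920) differed by −0.87 ± 0.20 log2 between mutant and wild type and did not pass the test (adjusted p = 0.081), with lower values in the mutant at all 4 times (−0.97, −0.23, −1.24 and −1.03). A second, dimmer MED16 probe gave 0.05, −0.17, −0.36 and 0.25, and the place of both probes relative to the insertion is not given in the sources used here. RPS2 (AT4G26090) differed by 0.11 ± 0.12, ICS1 (AT1G74710), the isochorismate synthase of salicylic acid synthesis, by 0.08 ± 0.26, and NPR1 (AT1G64280), a salicylic acid receptor and co-activator, by −0.12 ± 0.12; none passed the test. For the pathogenesis-related gene PR1 (AT2G14610) the mutant minus wild-type differences were 1.14, at least 2.85, 0.11 and −1.75 at 0, 4, 8 and 24 h, and for PR2 (AT3G57260), a glucanase, they were 1.43, 1.25, 0.64 and 0.24 (adjusted p = 0.64 and 0.085; fitted 0.59 ± 0.67 and 0.89 ± 0.21). PR5 had no gene-level value because both probes were marked as outliers on 1 array; they read −0.31 and −0.28 at 0 h, −0.68 and −0.73 at 4 h, and −1.74 and −1.77 at 8 h.

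Over all 4 times, the largest fitted loss in the mutant was that of EXLB1 (AT4G17030), an expansin-like protein, which was at least 350.2-fold lower (adjusted p = 0.00017), not well above background on any mutant array, and low with both of its probes. The plant defensin gene PDF1.2a (AT5G44420) was at least 25.5-fold lower (adjusted p = 0.0096). The subtilase gene ATSBT5.2 (AT1G20160) fell by 5.70 ± 0.18 log2 (adjusted p = 0.00029), AT5G05960 fell by 6.16 ± 0.26 and the iron superoxide dismutase gene FSD1 (AT4G25100) fell by 5.32 ± 0.50. AT2G37130 fell by 5.21 ± 0.66, and AT3G53980, AT5G51950, AT3G28840 and the galactinol synthase gene GOLS3 (AT1G09350) were at least 29.4-fold, 15.6-fold, 18.0-fold and 19.4-fold lower. Among genes higher in the mutant, BSMT1 (AT3G11480), which makes methyl salicylate from salicylic acid, rose by 3.50 ± 0.54 (adjusted p = 0.031), the NADPH oxidase gene RHD2 (AT5G51060), known from root hairs, by 2.92 ± 0.52, and the glutathione transferase gene GSTU25 (AT1G17180) by 2.52 ± 0.34. AT1G12030, AT1G11070, AT1G14120, AT4G36850 and AT3G10590 rose by 3.06, 3.04, 2.90, 2.88 and 2.60, and AT2G33850 and AT1G13608 were at least 5.04-fold and 5.88-fold higher. With dim values at the floor of their array RHD2, GSTU25, AT1G11070 and AT3G10590 read 2.69, 2.48, 2.59 and 2.30. RHD2 and GSTU25 were not well above background at 0 h in either genotype, and AT3G10590 was well above it on 1 wild-type array only.

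In limma, 181 genes were higher and 439 lower in the mutant (620 of 22567 tested, 2.75%), all 620 with 1 direction at all 4 times and 484 of them by 2-fold or more. The test itself favours genes with 1 direction. Of all tested genes 31.4% had 1 direction at all 4 times, where 4 independent pairs without a constant difference would give 12.5%. A constant difference between the slides would also raise this share. The counts fell to 73 higher and 159 lower without 0 h, 6 and 40 without 4 h, 47 and 169 without 8 h, and 31 and 90 without 24 h. With normal-exponential background correction 84.3% of calls were higher in the mutant, against 29.2%, and the median of all genes was 0.11 against −0.01. The share was 41.4% with the values of the deposited series. Among the 39 named genes past the threshold, 21 passed without 0 h, 10 without 4 h, 18 without 8 h and 20 without 24 h. Without an intensity trend in the variances 28 passed and 480 genes were called, 427 of them shared, and without a time term 4 of the 39 passed. EXLB1, AT5G05960, ATSBT5.2 and AT3G28840 passed in every alternative that tested them. Without 4 h, PDF1.2a, AT3G53980 and FSD1 no longer passed, nor did BSMT1 and AT2G33850 without 0, 4 or 8 h, or RHD2 without 0, 4 or 24 h. AT1G14120 did not pass without 4 or 8 h, AT3G10590 without 4 or 24 h, and AT2G37130 without 0 or 8 h. GOLS3, AT5G51950, GSTU25 and AT1G13608 lost the call with any 1 time left out. With normal-exponential correction GOLS3 and AT5G51950 no longer passed, and with quantile scaling AT2G33850, RHD2 and AT1G13608 did not.

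Some jasmonate/ethylene defence genes were lower in the mutant, mainly defensin genes and ORA59. Of 12 tested, 4 fell and 8 did not pass (1 higher and 8 lower when adjusted over the list alone): PDF1.2a, PDF1.2c (−3.67 ± 0.49), PDF1.3 (−3.40 ± 0.51), all defensins, and ORA59 (−4.53 ± 0.60), the AP2/ERF factor that activates them. With dim mutant values at the floor PDF1.2c, PDF1.3 and ORA59 read −3.31, −2.97 and −4.30, since 2, 1 and 2 of their mutant arrays were not well above background. ERF1, another activator of this branch, differed by 0.85 and did not pass. ERF2, ERF5 and ERF104 read −0.04, −0.34 and −0.33, also without passing. This list and the CBF list below were chosen with knowledge of published work on this mutant, so their counts are not independent evidence. The list median was −1.98, or −1.42 with dim values raised to the floor of their array. Camera gave an adjusted p of 5.9e-05, lost with an estimated correlation (adjusted p = 0.50), and fry gave 0.043. Fry gave 0.043 for the reference genes too, with 0 of 10 past the test, so it does not set this list apart from them. An exact sign-flip test over the 4 times gave p = 0.13, the smallest that 4 pairs allow. Among the 6 members well above background on all 8 arrays the median was −0.33 (adjusted p = 0.28). ORA59 no longer passed without 4, 8 or 24 h, nor PDF1.2c and PDF1.3 without 0, 4 or 8 h. Guard cell markers had a median of −0.42 and xylem markers of 0.73 in the contrast from which all list values between genotypes are taken.

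Some genes of the CBF cold regulon were lower too: 5 of 13 fell and 8 did not pass (1 higher and 6 lower when adjusted over the list alone). The dehydrin gene XERO2 fell by 4.14 ± 0.24, the drought- and cold-induced RD29A by 3.48 ± 0.25 (adjusted p = 0.0027 and 0.006), and GOLS3, KIN1 (−1.75 ± 0.18) and KIN2 (−1.70 ± 0.20) passed as well, while COR15A differed by −2.32 (adjusted p = 0.073). KIN1 and KIN2 lost the call without 4 h or 24 h. The CBF transcription factor genes themselves differed by 0.16 (CBF1), 0.96 (CBF2) and −0.41 (CBF3), none past the test. The median was −0.92, with camera at an adjusted p of 4.3e-05, lost with an estimated correlation (adjusted p = 0.50). Fry gave 0.043, as it did for the reference genes. XERO2 and RD29A passed with any 1 of the times left out.

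Several metabolic and signalling lists also differed by camera. None of the 11 aliphatic glucosinolate genes passed on its own (0 higher and 6 lower when adjusted over the list alone), with a median of −0.88 and values of −2.04 for MAM3, −1.63 for CYP79F1, −1.58 for BCAT4 and −1.38 for MYB76 (camera adjusted p = 7.3e-05; adjusted p = 0.52 with an estimated correlation; fry 0.16). On single arrays the median was −1.01, −1.39 and −1.39 at 0, 4 and 24 h but 0.25 at 8 h. Of 11 flavonoid genes, DFR (−2.75 ± 0.48) and UF3GT (−2.11 ± 0.39) fell (0 higher and 3 lower when adjusted over the list alone), each well above background on 1 mutant array; both lost the call with any 1 time left out, and UF3GT read 0.04 with normal-exponential correction. With dim values at the floor DFR and UF3GT read −1.63 and −1.25. The flavonoid median was −0.53, or −0.46 with dim values at the floor (camera adjusted p = 0.0086; adjusted p = 0.50 with an estimated correlation; fry 0.036). Among 19 genes of jasmonate synthesis, JAZ repressors and the MYC branch, the allene oxide cyclase gene AOC2 rose by 0.97 ± 0.14 (2 higher and 0 lower when adjusted over the list alone), and AOC3, VSP1 and JAZ10 read 1.24, 1.22 and 1.19 without passing. AOC2 lost the call with any 1 time left out. The median was 0.54 (camera adjusted p = 7.3e-05; adjusted p = 0.62 with an estimated correlation; fry 0.34).

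Few salicylic acid and SAR genes passed the test over all times. None of 12 genes of salicylic acid synthesis and the EDS1 node passed (2 higher and 0 lower when adjusted over the list alone; median 0.14; camera adjusted p = 0.035, adjusted p = 0.62 with an estimated correlation, and fry 0.48). Of 12 tested SAR output genes only AZI1, a lipid-transfer-like protein of SAR, fell, by 1.92 ± 0.24 (2 higher and 2 lower when adjusted over the list alone; median 0.90; camera adjusted p = 0.24). AZI1 read −1.51 with its dim 0 h value in the mutant at the floor, and lost the call without 4 h or 24 h and with normal-exponential correction. None of 10 positive SAR regulators passed, with a median of −0.05 (0.02 with the series value table), a mean of 0.12 and a camera adjusted p of 0.71, nor did any when adjusted over the list alone. None of 9 negative regulators passed either way, with a median of 0.53 (camera adjusted p = 0.013; adjusted p = 0.62 with an estimated correlation; fry 0.44). Both regulator lists were chosen with knowledge of published work on this mutant, so neither count is independent evidence.

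Xylem and guard cell markers differed by camera. Of 5 xylem markers the cysteine protease genes XCP1 (0.86 ± 0.11) and XCP2 (1.43 ± 0.12) rose (5 higher and 0 lower when adjusted over the list alone), and the cellulose synthase genes IRX3 and IRX5 read 0.73 and 0.60; the median was 0.73 (camera adjusted p = 4.3e-05; adjusted p = 0.50 with an estimated correlation; fry 0.043). XCP2 lost the call without 4 h and XCP1 with any 1 time left out. The 4 guard cell markers had a median of −0.42 with none past the test (0 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.031; adjusted p = 0.50 with an estimated correlation; fry 0.043). Photosynthesis genes had a median of 0.31, which was −0.05 with quantile scaling, with 0 of 23 past the test either way (camera adjusted p = 5.9e-05, adjusted p = 0.62 with an estimated correlation, and fry 0.34). At 0 h only 15 of the 23 had a usable difference between the 2 arrays, because the others were saturated. Saturated spots numbered 120 in the wild type and 48 in the mutant at 0 h, and 168 and 36 at 24 h. Saturation caps a signal, so this median may be shifted. Reference genes had a median of 0.10 (−0.02 with quantile scaling) and 0 of 10 past the test (camera adjusted p = 0.14; fry 0.043).

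**Figure D1:**
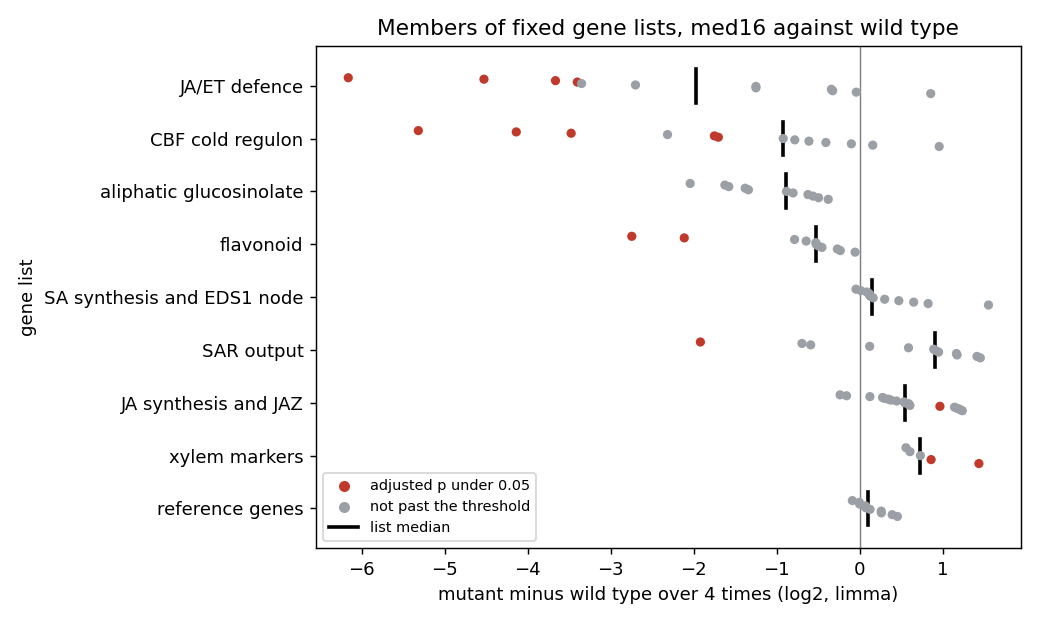
Each point is 1 gene, placed at its mutant minus wild-type difference over the 4 times (log2, limma, x axis), red where the adjusted p is under 0.05 and grey otherwise; bars mark list medians, with −1.98 for jasmonate/ethylene defence, −0.92 for the CBF cold regulon and 0.73 for xylem markers. Reference genes have a median of 0.10, which is −0.02 with quantile scaling.

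At 0 h the mutant already had at least 175-fold less EXLB1 signal and at least 70.8-fold less PDF1.2a. ATSBT5.2 was 59.8-fold lower, AT5G05960 91.4-fold and AT5G06570 at least 66.3-fold lower. RBOHB, an NADPH oxidase gene, was at least 38.7-fold higher, as were AT5G34865 (at least 60.1-fold), AT3G36659 (31.1-fold), AT5G48350 (at least 30.9-fold) and AT2G03560 (at least 30.5-fold). Jasmonate/ethylene genes had a median difference of −2.35 and CBF regulon genes of −1.48, both below all 10000 matched random lists, and SAR output genes had a median of 1.02, above all of them. Camalexin (−0.83), senescence (−0.74), clock (−0.46) and glucosinolate genes (−1.01) also lay below all matched lists, and iron genes (0.67) above all. In all, 617 genes were at least 2-fold higher and 947 lower (1564 of 20883, 7.49%), of which 284 were at a bound. With normal-exponential correction 54.2% of such genes were higher in the mutant against 39.5%. With 1 array a side there is no test at single times, and the random lists do not keep the correlation between members.

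At 4 h more genes were 2-fold apart than at other times. This order did not hold without the filter, where dim signals entered as read and not at a bound. The counts were then 4711 at 4 h, 6924 at 0 h and 7377 at 8 h. EXLB1 was at least 686-fold lower, GOLS3 at least 391-fold, AT5G51950 at least 233-fold, AT2G37130 223-fold and the nicotianamine synthase gene NAS3 86.2-fold lower in the mutant. Higher were AT5G28237 (22.8-fold), AT4G28088 (22.7-fold), BSMT1 (18.9-fold), AT5G39480 (at least 18.7-fold) and WRKY62 (16.5-fold), a WRKY factor among the negative SAR regulators. Of 19 genes of jasmonate synthesis and the MYC branch, 13 were at least 2-fold higher (median 1.29), and SAR output and negative SAR regulator genes had medians of 1.39 and 1.21, all above all 10000 matched lists. The jasmonate/ethylene and CBF medians were −2.30 and −1.57, below all of them, as was that of glucosinolate genes (−1.39), while iron genes (0.92) lay above all and xylem markers had a median of 0.89. The count was 1380 higher and 2267 lower (3647 of 21770, 16.8%), 634 at a bound. Higher genes made 37.8%, against 50.7% with normal-exponential correction and 54.0% with the series value table, where the median of all genes was 0.12 against −0.02.

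At 8 h, EXLB1 was at least 237-fold lower in the mutant, FSD1 159-fold, AACT1 at least 89.0-fold, AT4G08780 at least 40.3-fold and NAS3 at least 37.2-fold lower. BSMT1 was 26.7-fold higher, AT5G53905 at least 32.6-fold, AT4G08096 at least 28.7-fold and the phospholipase gene PLA2-GAMMA at least 21.7-fold higher. The only probe of SKS2 read 12.28 log2 higher and was saturated on the mutant array, while at 0, 4 and 24 h it read 0.21, −0.07 and 0.05. The SAR output and salicylic acid node medians were 0.06 and −0.01, those of jasmonate/ethylene and CBF genes −1.97 and −1.02, and that of xylem markers 0.96. Camalexin genes had a median of −0.51, below all matched lists, and jasmonate synthesis genes of 0.66, above all. There were 890 genes higher and 1113 lower (2003 of 20384, 9.83%), 485 at a bound. Of these, 44.4% were higher, against 65.2% with normal-exponential correction.

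At 24 h, EXLB1 was at least 529-fold lower in the mutant, AT3G53980 at least 173-fold, AT5G05960 105-fold, the beta-amylase gene BAM5 65.8-fold and ORA59 at least 60.4-fold lower. Higher were AT5G42510 (at least 144-fold), the purple acid phosphatase gene PAP20 (at least 54.9-fold), AT4G33320 (at least 45.5-fold), AT1G28650 (at least 30.3-fold) and RHD2 (24.8-fold). Jasmonate/ethylene genes had a median of −1.10 and glucosinolate genes of −1.39, both below all 10000 matched lists; the CBF median was −0.23, at percentile 1.41, and 0.00 with normal-exponential correction. Photosynthesis genes had a median of 0.65, above all matched lists, which was −0.04 with quantile scaling. SAR output genes had a median of −0.20 and negative SAR regulators of −0.32. There were 1078 genes higher and 1118 lower (2196 of 22563, 9.73%), 398 at a bound. Of these, 49.1% were higher, against 70.4% with normal-exponential correction.

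Whether the genotype difference changed from 0 h to the later times was tested with the interaction term. No gene passed in limma (0 of 22567, with 762 at an unadjusted p under 0.05 and a smallest adjusted p of 0.479). On simulated data this test recovered 0% of genes changed by 1 log2 unit and 19.4% at 2. Changes of that size could therefore be missed. As lists, jasmonate synthesis with the MYC branch had a median interaction of 0.95 (camera adjusted p = 1.8e-10, and adjusted p = 0.85 with an estimated correlation), with LOX3 at 2.25 ± 0.42, AOC3 at 1.98 ± 0.67 and JAZ8 at 1.84 ± 0.42. Camalexin genes had one of 0.82 (adjusted p = 5.9e-05, and adjusted p = 0.85 with an estimated correlation), with PAD3 at 1.53 ± 0.56 and CYP81F2 at 1.44 ± 0.51. At 0 h PAD3 and CYP71A13 in the mutant and CYP71A12 in both genotypes were not well above background, so their responses are read against background signal. The endoplasmic reticulum folding list had a median of −0.50 (adjusted p = 0.0043, and adjusted p = 0.85 with an estimated correlation), led by the chaperone gene BIP3 at −1.13 ± 0.51. The CBF regulon had 0.51 (adjusted p = 0.023) and senescence genes 0.62 (adjusted p = 0.025), each with adjusted p = 0.85 with an estimated correlation. Between the genotypes at 0 h, the medians of camalexin and senescence genes were −0.83 and −0.74. None of the 5 lists passed by fry (0.95), and 0 of their genes passed. When adjusted over the list alone, jasmonate synthesis had 2 genes higher and 0 lower, senescence 1 and 1, and the other 3 lists 0.

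At 4 h against 0 h, with genotype as a block, genes of salicylic acid synthesis and camalexin had risen together. All 12 genes of the salicylic acid and EDS1 node rose, among them PBS3 (6.40 ± 0.42), which conjugates isochorismate, the transporter gene EDS5 (5.78), ALD1 (7.77 ± 0.56) of pipecolate synthesis, and FMO1, which hydroxylates pipecolate, at least 436-fold. PAD3, the last enzyme of camalexin synthesis, rose by 10.07 ± 0.49 (adjusted p = 6e-05) and led a list in which 9 of 11 rose (10 when adjusted over the list alone), with GSTF7 at 6.92 and CYP81F2 at 6.56. The metacaspase gene MC8 rose by 9.87 ± 0.33, and AT4G11170, PROPEP3, the precursor of a damage peptide, and WRKY75 were at least 256-fold, 233-fold and 305-fold higher. The largest fitted falls included SAUR27 (−5.05 ± 1.14) of the auxin-induced SAUR family, AT1G29490 (−4.98 ± 0.98), AT4G28780 (−4.83 ± 0.76), the expansin gene EXPA8 (−4.79 ± 0.97) and AT1G52750 (−4.79 ± 0.73). SAUR27, AT1G29490 and AT1G52750 were not well above background in the mutant at 4 h, and read −4.74, −4.72 and −4.79 with dim values at the floor.

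Counts at 4 h differed between the other lists. SAR output genes rose in 9 of 12 cases, UGT76B1, a glucosyltransferase acting on defence signals, by 8.15, GRX480 by 6.33 and AZI1 by 6.05 (5.24 with its dim 0 h value at the floor), while PR1 read 0.45 and did not pass. Of the SAR regulators, 8 of 10 positive ones rose, with WRKY54 at 4.72, WRKY18 at 4.56 and WRKY70 at 4.08, and 7 of 9 negative ones, with WRKY62 at 6.82 and NIMIN2 at 5.96, while SNI1 (−1.26) and NIMIN3 (−0.80) fell, the latter not past the test without 8 h or 24 h. These lists were chosen with knowledge of published work on this mutant, so their counts are not independent evidence. Of 19 genes of jasmonate synthesis and the MYC branch 15 rose (17 when adjusted over the list alone), with AOC3 at 5.81 and LOX4 at 4.58. Among defence genes of the jasmonate/ethylene branch 5 of 12 rose, ERF1 by 6.31 ± 0.45. Pattern-triggered signalling rose in 14 of 16 genes (NHL10 8.88, WRKY40 6.84, FRK1 6.83), and AvrRpt2 recognition in 3 of 3 (RPS2 1.98, RIN4 1.23). Heat-shock genes rose in 6 of 7 (HSFA2 5.11), touch genes in 5 of 6 (6 when adjusted over the list alone; ZAT12 5.87) and endoplasmic reticulum folding in 8 of 13 (BIP3 2.06). Phenylpropanoid genes rose in 8 of 13 cases (9 when adjusted over the list alone; CAD5 3.73, PAL1 3.03), and senescence genes in 6 of 10 (7 when adjusted over the list alone; SAG21 6.81, SAG13 4.65). Of the CBF cold regulon, 6 genes rose and 2 fell (RD29A 3.18, XERO2 2.73). In limma 4016 genes rose and 5599 fell (9615, 42.6%). The median of all genes was −0.20, against which changes are to be read, and −0.05 with normal-exponential correction.

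At 8 h the largest fitted rises were those of FMO1, at least 8736-fold (adjusted p = 1.7e-05), AT3G13610 (at least 3432-fold), the acireductone dioxygenase gene ARD3 (12.62 ± 1.44), PAD3 (12.35 ± 0.49) and UGT76B1 (11.88 ± 0.75). At 0 h FMO1 and AT3G13610 in both genotypes, ARD3 in the wild type and PAD3 in the mutant were not well above background, so these genes are not ranked; ARD3 read 12.06 with dim values at the floor. PR1 had risen by 10.04 ± 0.95 and PR2 by 3.50, with 11 of 12 SAR output genes higher and DIR1 lower (−1.41). All 12 salicylic acid node genes were higher (ALD1 11.75, PBS3 7.68, EDS5 6.41). Also higher were 8 of 10 positive SAR regulators (9 when adjusted over the list alone), 8 of 9 negative ones (WRKY62 7.64, NIMIN2 7.41), 10 of 11 camalexin genes (CYP71A13 11.63, or 11.47 with dim values at the floor) and 12 of 19 jasmonate synthesis genes (AOC3 5.81, JAZ5 4.76). The 13 endoplasmic reticulum folding genes and 7 heat-shock genes all rose, BIP3 by 5.86 ± 0.40, BIP2 by 4.83, PDIL1-2 by 4.53, HSP17.6II by 7.04 ± 0.51 and HSP90.1 by 6.10. Of 12 jasmonate/ethylene defence genes, 6 rose, ERF1 by 4.84 and PR4 by 3.53, and 2 defensin genes fell, PDF1.3 by 2.77 and PDF1.2c by 2.54, neither well above background in the mutant at 8 h (1.90 and 1.82 with dim values at the floor).

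Photosynthesis genes fell at 8 h. The largest fitted falls of single genes included AT5G48490 (−9.92 ± 0.46), SAUR68 (at least 537-fold), AT5G02760 (−9.01 ± 0.59), AT5G50740 (−8.89 ± 0.45) and SAUR29 (at least 433-fold). AT5G02760 and AT5G50740 were not well above background in the mutant at 8 h, and read −8.64 and −8.46 with dim values at the floor. Of 23 photosynthesis genes 22 fell, the light-harvesting genes LHCB2.2 by 4.66 ± 0.35, LHCB1.1 by 3.95 and LHCB2.1 by 3.65. At 4 h 9 had fallen (8 when adjusted over the list alone), including LHCB1.1 at −1.24, which read 0.06 with the series value table. Aliphatic glucosinolate genes fell in 9 of 11 cases and 1 rose (CYP79F1 −3.32, MYB29 −3.28, MAM1 −2.89). Flavonoid genes fell in 5 of 11 cases with 1 rise (TT4, chalcone synthase, −4.80; 4CL3 −3.90), and iron genes in 6 of 15 with 2 rises (BHLH100 −4.03, or −3.38 with dim values at the floor, BHLH101 −3.65; 1 rise when adjusted over the list alone). BHLH100 did not pass without the 4 h arrays. All 5 epidermis markers fell (FDH −2.78), as did all 5 xylem markers (IRX1 −1.25), 2 of 4 guard cell markers (MYB60 −2.28, GC1 −2.19) and 2 of 4 phloem markers (SULTR2;1 −1.49; 1 when adjusted over the list alone). In limma 6070 genes rose and 7726 fell (13796, 61.1%). The median of all genes was −0.19, −0.08 with quantile scaling and 0.00 with the series value table.

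At 24 h the largest fitted rises included KTI1, a Kunitz trypsin inhibitor, at 11.37 ± 1.17 (adjusted p = 0.00059), the protease inhibitor gene UPI at 10.50 ± 0.73 and AT4G12490 at 10.42 ± 0.96. None of the 3 was well above background in the mutant at 0 h, so they are not ranked; with dim values at the floor they read 10.52, 9.38 and 10.34. FMO1 and GSTU3 were at least 1045-fold and 360.1-fold higher. SAR output stayed high, with 10 of 12 genes risen (PR1 9.94, NIT2 9.31, UGT76B1 7.01, PR2 5.99). The same held for the salicylic acid node (12 of 12; ALD1 8.75, PBS3 5.77), positive and negative SAR regulators (8 of 10 and 7 of 9), camalexin (9 of 11; CYP71A13 8.58, or 8.42 with dim values at the floor), folding (13 of 13; BIP3 6.82) and heat-shock genes (7 of 7). Of 13 CBF regulon genes 11 fell (12 when adjusted over the list alone), COR15B by 5.95 ± 0.60, CBF3 by 3.97 and CBF1 by 3.86. Of 23 photosynthesis genes 21 fell (23 when adjusted over the list alone), LHCB1.3 by 2.68 and LHCA3 by 2.24. Among the largest fitted falls were those of the desaturase gene ADS1 (at least 326-fold), the auxin-response repressor gene IAA29 (−9.39 ± 0.61, or −9.29 with dim values at the floor), AT5G57760 (−9.23 ± 0.53), KCS8 (−9.16 ± 0.55) and AT2G10940 (−9.31 ± 1.03), for which 2 further probes disagreed. All 5 epidermis markers (CER1 −2.83, FDH −2.32), 3 of 4 guard cell markers (GC1 −2.12; 1 higher and 3 lower when adjusted over the list alone) and 3 of 5 xylem markers fell. In limma 4844 genes rose and 6417 fell (11261, 49.9%). The median of all genes was −0.14, −0.31 with normal-exponential correction and 0.02 with the series value table.

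**Figure D2:**
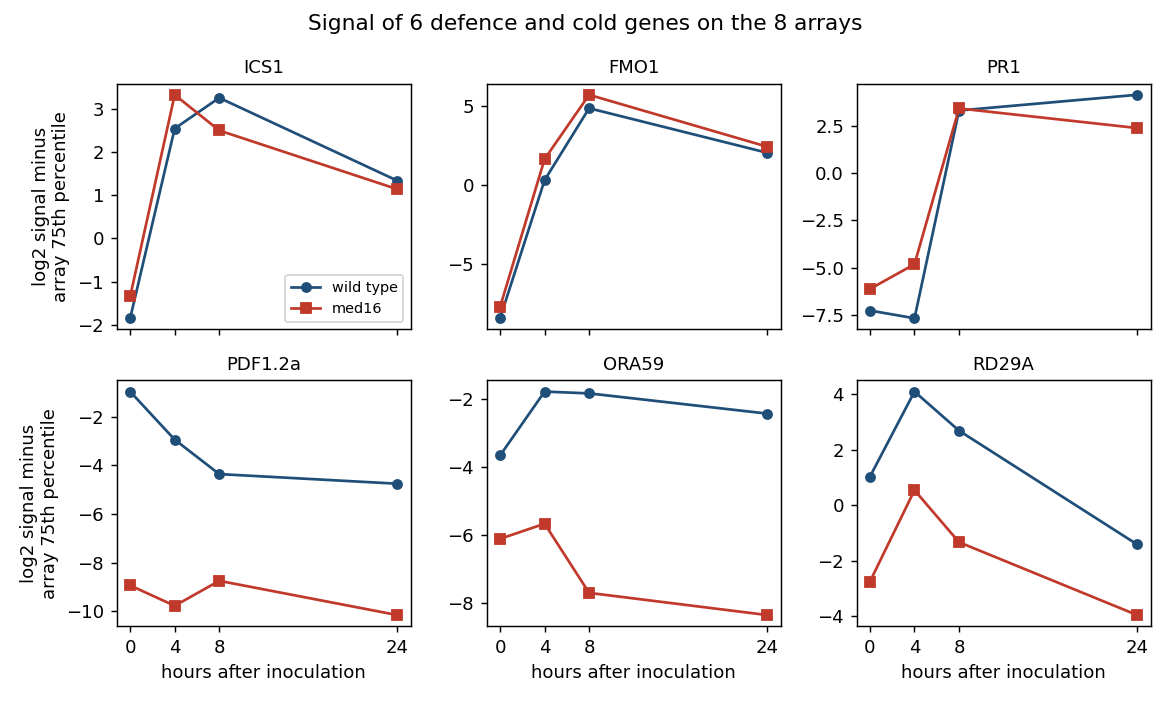
The 6 panels show log2 signal minus the array's 75th percentile (y axis) against hours after inoculation (x axis) for ICS1, FMO1, PR1, PDF1.2a, ORA59 and RD29A, 1 array per point, wild type as blue circles and the mutant as red squares. FMO1 was not well above background at 0 h in either genotype, PDF1.2a was well above background on 0 and ORA59 on 2 of the 4 mutant arrays, and PR1 on 3 of the 4 wild-type arrays; PR1 differed between genotypes by at least 2.85 at 4 h and −1.75 at 24 h.

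Within each genotype, the response can be read from single arrays, untested. The salicylic acid node had a median of 4.95 in the wild type and 5.13 in the mutant at 4 h, 5.19 and 4.75 at 8 h, and 3.77 and 3.32 at 24 h. SAR output genes read 2.45 and 2.24, 6.35 and 5.27, and 6.49 and 5.00 at the same times. Jasmonate synthesis genes read 1.32 in the wild type and 3.34 in the mutant at 4 h, 1.66 and 2.44 at 8 h, and 1.05 and 1.74 at 24 h, and CBF regulon genes −3.07 and −1.95 at 24 h. Aliphatic glucosinolate genes read −3.06 in the wild type and −1.44 in the mutant at 8 h. In the wild type 3099 genes were at least 2-fold higher and 2860 lower at 4 h, 5069 and 6403 at 8 h, and 3943 and 5190 at 24 h. With the 1.5-fold rule the wild type at 4 h had 4290 higher and 6072 lower. In the mutant the 2-fold counts were 3888 and 5025, 4434 and 5748, and 3616 and 5209. At a bound were 690, 1454 and 1269 of the wild-type and 1035, 1477 and 932 of the mutant genes. With the values of the deposited series, 51.7% of the mutant's changed genes at 24 h were higher, against 41.0%.

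**Figure D3:**
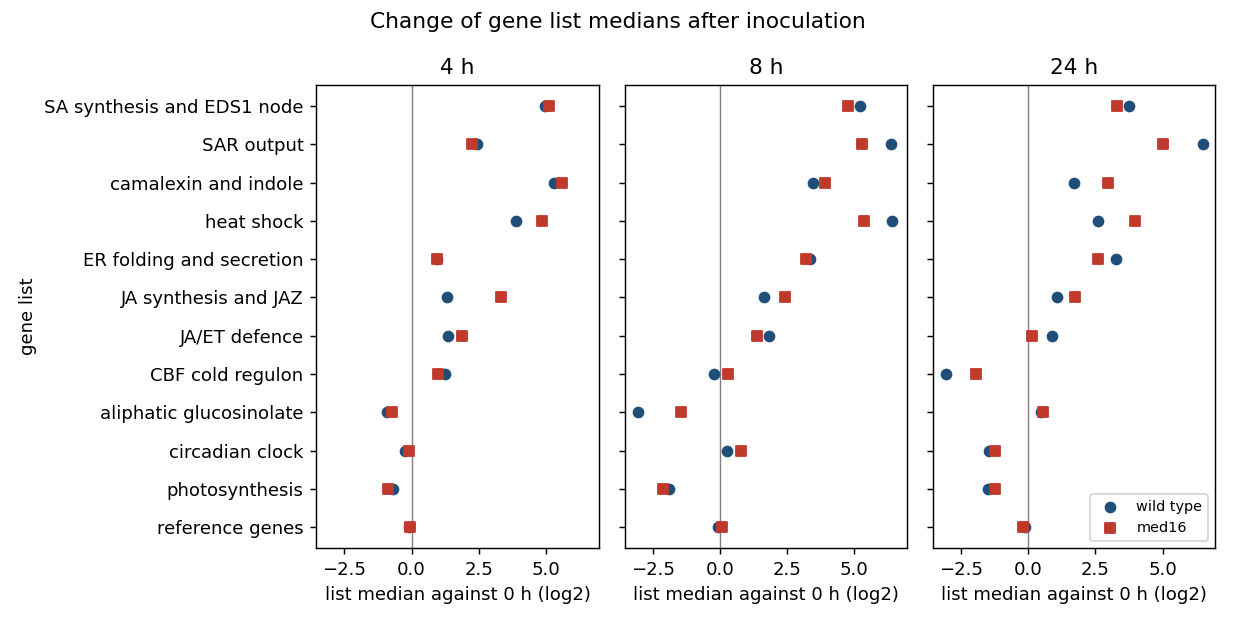
List medians against 0 h (log2) are shown at 4, 8 and 24 h for wild type and mutant, 1 array per genotype and time and no test. The salicylic acid node lies at 4.95, 5.19 and 3.77 in the wild type and 5.13, 4.75 and 3.32 in the mutant, and photosynthesis genes at −1.90 and −2.10 at 8 h; reference genes lie at −0.06 and 0.08 at 8 h, where the wild-type median is 0.01 with quantile scaling.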

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

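The tests chosen only after the result was seen were the limit to the 8 splits that part all time pairs, the shares of calls by direction in 3 equal groups of genes by brightness, the correlation of the 4 h difference with the later response, and the jasmonate/ethylene median with dim values raised to the floor.

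The genotype difference of 620 genes was tested against regrouping, spot-level, brightness and linkage explanations. Only 8 splits of the arrays part all 4 time pairs as the real one does, too few for a share under 0.05; 1 of the 8, the real one, gave as many genes, with 620 against 0 as the highest other, and the 24 further splits that could be fitted part only 2 time pairs, hold time differences in their residual and called no gene, so the share of 1 in 32 fitted splits, which met the bound set beforehand, was not relied on. Spot-level differences between the slides are argued against by a further probe of 144 called genes, which had the sign of the call in 142 (98.6%, exact 95% interval 95.1 to 99.8%). An intensity-dependent difference between the slides stays open: calls went both ways in each of 3 equal groups by brightness, with at least 23.1% in the rarer direction, but with normal-exponential correction this was 3.27% in the dimmest group. For a segment of another accession around MED16, 3 of 118 tested genes within 200 loci of it were called. The odds ratio was 0.923 (0.187 to 2.78, Fisher's exact p = 1). This argues against a strong excess of calls in that window only. A smaller excess, or a segment reaching beyond the window, was not excluded. The med16 genotype may account for these genes. It cannot be told apart from the intensity-dependent difference, or from growth, RNA preparation and hybridisation of the mutant set on its own slide. The same holds for a segment that the linkage test could not exclude.

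At 4 h, 3647 genes were at least 2-fold apart between the genotypes, against 2003 at 8 h, and 2244 against 1617 with normal-exponential correction. Without the filter, where dim signals entered as read and not at a bound, the counts were 4711 and 7377. The excess at 4 h was then lost, with 77.3% of the 8 h genes higher in the mutant. The lowest well-above-background signals of the 8 h arrays differed, at −6.78 (mutant) and −7.94 (wild type). For genes well above background on all 8 arrays, array brightness as the cause is argued against, since the count was 2405 at 4 h, 1.85 times the 1303 at 8 h. The mutant array might be further along the response, since across genes, which are not independent replicates, the 4 h difference correlated with the wild-type change from 0 to 8 h at r = 0.408 (Spearman 0.464; r = 0.111 for the 24 h difference), a value between both bounds of the test, so this stays open. With the mutant change from 0 to 8 h the correlation was 0.435. Among the 3910 tested genes at least 2-fold apart at 4 h, with signals as read, it was 0.484 with the wild-type change. The wild-type 4 h array might equally lie behind in the response. A faster response in the mutant and a difference in sampling or inoculation of either 4 h pool cannot be told apart.

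Jasmonate/ethylene defence genes had a median of −1.98 between mutant and wild type. With dim values raised to the floor of their array the median was −1.42, between PDF1.1 (−1.59) and CHI-B (−1.25). Signal below that floor therefore does not account for the whole difference. The floor is the lowest well-above-background signal of an array, and dim probes can read above it. A higher floor was not tried, so the test does not decide whether dim signal sets the fold. Whether dim probes as such are the cause stays open: the 6 members well above background on all 8 arrays had a median of −0.33, inside the bound set beforehand for that cause, but the filter itself removes the defensin genes that fell to background, so the test decides nothing. A loss of Mediator-dependent activation of this branch is a candidate explanation that no test here separates from the slide.

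Some lists differed between genotypes in their change from 0 h to the later times by camera on the interaction term, with adjusted p = 0.85 for each with an estimated correlation. The medians were 0.95 for jasmonate synthesis and the MYC branch, 0.82 for camalexin, −0.50 for endoplasmic reticulum folding, 0.51 for the CBF regulon and 0.62 for senescence genes. Other medians went opposite ways in the genotypes, and these differences were not tested. CBF regulon genes at 8 h against 0 h read 0.31 in the mutant and −0.23 in the wild type. Flavonoid genes at 24 h read −0.12 in the mutant and 0.61 in the wild type, with 0.06 in the mutant in the series value table. Iron genes at 24 h read −0.62 in the mutant and 0.08 in the wild type, which was −0.13 with normal-exponential correction. Epidermis markers at 4 h read −0.58 in the mutant and 0.12 in the wild type. Mediator genes at 8 h read 0.021 in the mutant, −0.02 with normal-exponential correction, and −0.16 in the wild type. Reference genes at 8 h read 0.078 in the mutant and −0.06 in the wild type, which was 0.01 with quantile scaling. Touch genes at 24 h read 0.22 in the mutant, −0.21 with normal-exponential correction, and −0.50 in the wild type. PR1 at 4 h against 0 h read 1.31 in the mutant and −0.41 in the wild type, where it was not well above background at 4 h, so its direction there is not known. PDF1.2a at 8 h read 0.19 in the mutant, where it was not well above background, and −3.40 in the wild type.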

How the results depend on the processing

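The normal-exponential version alone was chosen after seeing the data; the version on mean spot signals was not run, as that column is not in the files used here, and slide as a block was not possible because each slide held 1 genotype. Of 168 recomputed counts 136 stayed within 1.5 times of the reported one. Of 7213 tests of named genes and lists 6860 kept their side of the threshold, 261 lost and 85 gained the call. A further 7 reversed with a call in at least 1 version. Among the 6860, 61 changed sign without a call in either version. Of 2069 single-array differences and medians 1957 moved by under 1.5-fold, and of 80 list tests 57 kept their call. The call of 620 genes between genotypes rests on few arrays. Dim signals limit the folds, since 67.9 to 79.0% of spots were well above background. Unless said, the cause was not tested.

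Leaving out 1 time (leave-one-out) gave 6 to 73 genes higher and 40 to 169 lower in the mutant, with fewer arrays and 2 residual degrees of freedom. Without a time term 0 were higher and 4 lower, because time differences then stand in the residual. With time as a random block 447 were higher and 736 lower.

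With normal-exponential correction 3823 genes were higher and 712 lower between genotypes, sharing 500 of the 620 genes; 3228 of the higher ones lay among the dimmest of 3 equal groups of genes by brightness, whose median was 0.49. At 0 h 994 and at 4 h 2244 genes were then 2-fold apart, and 8 lists passed for the interaction instead of 5. List medians that lost the call were 0.21 for the salicylic acid node, 0.54 for negative SAR regulators, 0.57 for jasmonate synthesis (adjusted p = 0.054), 0.28 for photosynthesis and −0.12 for flavonoids. Reversed values were UF3GT between genotypes at 0.035, COBL9 at 0.89 against −0.04, and GL3 at 24 h at −0.20 against 2.18.

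Quantile scaling reversed UBQ10 at 24 h (0.41 against −0.67) and the photosynthesis median between genotypes (−0.045), and the salicylic acid node at 0.14 lost its call (adjusted p = 0.093). The series value table reversed LHCB1.1 at 4 h (0.059), and the node at 0.25 lost its call. The mean of all probes reversed UBQ10 (0.070) and SCR at 24 h (−0.18 against 0.77), and the node at 0.16 lost its call.

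With the filter for all 8 arrays, which tests fewer genes, 1006, 2405, 1303 and 1219 genes were 2-fold apart between genotypes at 0, 4, 8 and 24 h, and the medians of the node (0.12), jasmonate/ethylene genes (−0.33) and flavonoids (−0.49) lost their calls. Leaving out the filter added dim genes, and in single-array counts dim signals were then taken as read and not at a bound. At 0, 8 and 24 h 6924, 7377 and 3329 genes were then 2-fold apart, 79.2% and 77.3% of them higher in the mutant at 0 and 8 h. In the mutant 14114 genes changed at 24 h, and the node at 0.14 lost its call. The wider 1.5-fold rule gave 4069, 7712, 4638 and 5085 genes between genotypes at 0, 4, 8 and 24 h and 10362 for the wild type at 4 h.

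With an estimated correlation 0 of 10 lists passed between genotypes (camera adjusted p 0.50 to 0.62) and 0 of 5 for the interaction. The medians stay by construction at 0.14, 0.53, −1.98, 0.54, −0.92, 0.31, −0.53, −0.88, −0.42 and 0.73 for the salicylic acid node, negative SAR regulators, jasmonate/ethylene, jasmonate synthesis, CBF regulon, photosynthesis, flavonoids, glucosinolates, guard cells and xylem. Correlation between members is not shown to be the cause, since this version also rests on few residual degrees of freedom. Flavonoid genes and guard cell markers had estimated correlations of −0.07 and −0.11, below the preset 0.01. Their unadjusted camera p still rose from 0.0023 to 0.049 and from 0.011 to 0.081.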

Other observations

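No test in this part was chosen only after the result was seen, but values with normal-exponential correction come from an alternative chosen after the data were seen.

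Most clock genes differed at 24 h from 0 h, although both harvests nominally fall at the same time of day; harvest clock times are not given in the sources used here. Of 14 clock genes 4 were higher and 9 lower at 24 h (4 and 10 when adjusted over the list alone), with PRR3 at −4.86, PRR5 at −4.61, ELF4 at −4.02 and the RNA-binding GRP7 at −5.65 ± 0.45. At 8 h 5 were higher and 4 lower (6 and 4 when adjusted over the list alone), with ELF4 at 3.79 and CCA1 and LHY, the morning MYB factors, at −3.61 and −2.76; at 4 h 1 was higher and 1 lower. Aliphatic glucosinolate genes, 9 of which were lower at 8 h, had 3 higher and 0 lower at 24 h (1 and 0 when adjusted over the list alone; MAM3 2.08, not past the test without 4 h or 8 h), and 0 and 2 at 4 h. Flavonoid genes had 0 higher and 2 lower at 4 h (0 and 1 when adjusted over the list alone) and 3 and 1 at 24 h, with the anthocyanin activator PAP1 at 4.63. Jasmonate/ethylene genes had 4 higher and 1 lower at 24 h (3 and 0 when adjusted over the list alone), with a median of −0.09 and a mean of 0.29, and jasmonate synthesis genes had 9 and 1. CBF regulon genes had 2 higher and 2 lower at 8 h (2 and 0 when adjusted over the list alone).

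Senescence genes had 7 higher and 2 lower at 8 h and 8 and 1 at 24 h, with SAG13 at 6.99 and 8.70. Pattern-triggered signalling genes had 12 and 3, then 10 and 3 (11 and 4 when adjusted over the list alone), with NHL10 at 11.23 and 8.59 and FRK1 at 8.19 and 6.15. The 3 recognition genes all rose at 8 h, and 1, RPS2, passed at 24 h (3 when adjusted over the list alone). Phenylpropanoid genes had 2 higher and 1 lower at 8 h and 8 and 0 at 24 h, with CAD5 at 2.85 and 3.20, and touch genes 3 and 1 at 8 h and 2 and 3 at 24 h, with a median of −0.01 and a mean of 0.34 at 24 h. Iron genes had 0 called at 4 h and 2 higher and 0 lower at 24 h (1 and 0 when adjusted over the list alone). Mediator genes had 1 higher and 3 lower at 4 h, 5 and 4 at 8 h, and 1 and 4 at 24 h (1 and 2, 4 and 3, and 1 and 4 when adjusted over the list alone), with MED16 itself among those higher at 1.46, 2.35 and 1.15. Its second probe read 0.39 in the mutant and 0.60 in the wild type at 4 h, 1.32 and 1.73 at 8 h, and −0.07 and −0.28 at 24 h. Reference genes had 0 and 1, 1 and 2 (1 and 1 when adjusted over the list alone), and 1 and 3, with the tubulin gene TUB2 at −0.88, −1.89 and −1.40, and UBQ10 at 24 h at −0.67 but 0.41 with quantile scaling. Guard cell markers had 0 higher and 2 lower at 4 h, epidermis markers 0 and 2, xylem markers 0 and 3 and phloem markers 0 and 1. Of 2 trichome markers GL2 fell at 8 h (−2.29; 1 higher and 1 lower when adjusted over the list alone) and GL3 was higher at 24 h (2.18, or 1.05 with dim values at the floor, −0.20 with normal-exponential correction, and not past the test without 4 h); of 2 root markers SCR was higher at 24 h (0.77, −0.18 with the mean of all probes).

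Between genotypes, the lists not yet described had few calls. Iron genes had FER4, a ferritin, at −1.59 ± 0.29 as their only call among 15 (1 higher and 2 lower when adjusted over the list alone; median 0.35; camera adjusted p = 0.49), with BHLH38 at 2.07 and BHLH39 at 2.08 not past the test. Pattern-triggered signalling genes had PHI-1 at 1.25 ± 0.22 and WRKY29 at −1.42 ± 0.23 past the test among 16 (1 and 3 when adjusted over the list alone; median −0.05, 0.02 with the series value table). The lignin gene CAD5 fell by 0.81 ± 0.13 among 13 phenylpropanoid genes (1 and 1 when adjusted over the list alone; median 0.19), the calmodulin-like TCH2 rose by 1.09 ± 0.14 among 6 touch genes (median 0.22), and the sulfate transporter gene SULTR2;1 fell by 0.94 ± 0.17 among 4 phloem markers (0 and 2 when adjusted over the list alone; median −0.19). FER4, PHI-1, WRKY29, CAD5, TCH2 and SULTR2;1 each lost the call in at least 3 of the 4 fits with 1 time left out. No gene passed among 11 camalexin genes (median −0.21), 3 recognition genes (0.11), 13 folding genes (0.05, −0.01 with normal-exponential correction), 14 clock genes (−0.07, 0.01 with the series value table), 19 Mediator genes (−0.10), 10 senescence genes (0.02, with camera pointing down, −0.03 with quantile scaling), 7 heat-shock genes (−0.08, with a mean of 0.14, and 0.16 with normal-exponential correction), 5 epidermis markers (0.15), 2 trichome markers (0.26) and 2 root markers (0.00). When adjusted over the list alone, 1 folding gene was higher, 1 camalexin and 1 trichome gene were lower, and clock and senescence genes had 1 higher and 3 lower and 1 and 1. Camera gave adjusted p values between 0.14 and 0.94 for the lists of this paragraph, apart from the trichome and root markers, which were too few for it.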
